A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

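The series holds 5 one-colour Affymetrix yeast arrays, 3 of the wild-type strain BY4741 and 2 of the isogenic Δrsf2 strain, both grown on glycerol as the only carbon source. Groups and replicate numbers were taken from the sample titles, which call the samples biological replicates. Per the labels, nucleic acids were extracted with hot phenol, poly(A) RNA was selected on oligo(dT) resin, and biotin-labelled material was hybridised. The text for treatment in the labels describes a move from dextrose to glycerol medium for a set number of minutes, which the series design does not include, and no such time was used. The deposited values are linear signal intensities, 1 per probe set, which the authors made with MAS5, per the submitters' processing notes. The version of MAS5, its settings and any detection calls were not given in the sources used here.

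The deposited signals were checked before any test. Their 2% trimmed means were 500.7, 500.4 and 500.3 in wild-type replicates 1 to 3, 100.1 in Δrsf2 replicate 1 and 500.3 in Δrsf2 replicate 2, so 1 array had been scaled to a different target. By a rule fixed before the data were examined, trimmed means that differ by more than 10% led to quantile normalisation. Each array was scaled to a trimmed mean of 500 and the 9275 probe sets that are not controls were quantile normalised. This assumes one distribution of signals for all arrays, so a change in total mRNA per cell cannot be seen. A floor at the 10th percentile of the values of single-gene probe sets (29.5) was applied, and log2 was taken. The floor is a percentile and not a detection limit, so a fold against a group at the floor is a lower bound. In the 5 arrays 8.29% to 13.1% of these probe sets lay under the floor.

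Of 9335 probe sets, 60 were controls, 6504 had 1 gene in the platform annotation, 328 had several and 2443 had no listed gene. All 6504 were matched by gene identifier to the yeast gene table of assembly R64, which served only for names and neighbours. No genome build was named for the array, so no coordinates are given. Of 5656 genes 315 had more than 1 probe set, and the one with the highest mean was used. Genes with a mean log2 signal under the 25th percentile (a signal of 130) were left out, with RSF2 kept by exception, which left 4243 genes. Probe sets marked as possibly shared between genes, such as those of RDN18-1, YHB1, HXT6 and HXT7, can bind related transcripts. Probe sets of several genes were not named, and control probe sets were used only as quality values.

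The groups were compared on the log2 scale with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with trend, over all 5 arrays with group as the only term. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. A size rule counted genes with at least a 2-fold difference and no overlap between groups. Errors of fitted differences are SE, and group means are of normalised signals with SD. Named genes were fixed by rule: RSF2 and its neighbours, the 12 higher and 12 lower genes of smallest p among those at least 2-fold apart without overlap, and up to 3 genes of smallest p in each list. The 35 gene lists were also fixed beforehand, and the 31 lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the 31. Estimated correlations and fry, both in limma, were alternatives. Single names outside the rule are said to be chosen after their values were seen, or come from the fits with 1 mutant array.

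The fit was tested on simulated data with 4243 genes, 200 of them changed, in 10 draws. With the spread of the 5 arrays it found 5% of genes changed 2-fold, 61% at 4-fold, 96.6% at 8-fold and 99.2% at 16-fold, with 8 false calls per draw. With the spread of the wild-type arrays it found 29.4% at 2-fold and 97.8% at 4-fold, with 11.2 false calls. The changed genes were split evenly over these sizes, and both groups were given the same spread. In the real arrays the median SD per gene was 0.57 in Δrsf2 and 0.33 in the wild type on the log2 scale. These shares need not hold for the real comparison. There RSF2, HPF1 and RDN18-1 were each over 8-fold lower and had a limma adjusted p of 0.154. Camera found a list of 20 genes shifted by 0.7 on the log2 scale in 10 of 10 draws and an unshifted one in 0. Genes varied independently of each other in these draws. The result therefore does not cover lists whose members vary together, and does not bear on the preset correlation.

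Array quality was read from control probe sets. The CreX spike-in, scaled like the array, was 56025 in wild-type replicate 1 and 59709 in Δrsf2 replicate 1, against 9393, 3417 and 2715 in wild-type replicates 2 and 3 and Δrsf2 replicate 2. These 2 sets of arrays were treated as a technical batch that holds both groups, defined from the data. The ratio of 3' to 5' signal of ACT1 was 2.76, 2.28 and 1.69 in the wild type and 4.91 and 1.55 in Δrsf2. Settings fixed beforehand for comparison were the normalisation, the floor, the signal filter, the choice of probe set, the variance model, array weights, a replicate block, each array left out, and the thresholds. Equal scaling without quantiles, leaving out both arrays of high spike-in signal, and a spike-in block were added after seeing the data.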

Results

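Transcript levels were measured in Saccharomyces cerevisiae BY4741, a common haploid laboratory strain, and in an isogenic strain that lacks RSF2 (YJR127C, also called ZMS1), which encodes a zinc-finger protein. Both strains grew on glycerol, a carbon source that yeast can use only by respiration, in 50 ml of rich medium to an A600 of 0.6. Poly(A) RNA of 3 wild-type and 2 Δrsf2 biological replicates was hybridised to 1 array each, and signals are in arbitrary units after normalisation. The single comparison asks which transcripts depend on RSF2 during respiratory growth on glycerol. The small number of arrays limits the precision of every value, and 4243 genes entered the test.

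RSF2 itself came first, as a check of the labels. Its normalised signal was 293 ± 45.1 (SD, n = 3) in the wild type, while both Δrsf2 arrays lay at the floor of 29.5, so the transcript was at least 9.86-fold lower in the mutant. The deposited signals were 203.8, 253.9 and 415.9 in the wild type against 1.9 and 3.3 in Δrsf2, and all 5 labels therefore match the genotype. The fitted log2 difference was -3.30 ± 0.44 (SE), with a limma adjusted p of 0.154. Without the floor the difference was -6.05 and the adjusted p 0.0311, and leaving out Δrsf2 replicate 1 or 2 gave 0.0144 or 0.0162, within a range of 0.0144 to 1 over 20 alternative settings.

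Among the neighbours of RSF2 on the chromosome, ENT3, which encodes an epsin-like protein, had a log2 difference of 0.08 ± 0.39 (SE), and STR2, cystathionine gamma-synthase, one of 0.47 ± 0.45. VPS70 was at -0.42 ± 0.37 and EFM3 at -0.31 ± 0.46, and limma adjusted p-values for these 4 genes ran from 0.966 to 0.991. The sign turned under some settings for 3 of them: ENT3 and STR2 were at -1.09 and -0.68 in the values as deposited, where the median of all genes moved by -1.11. ENT3 was also at -0.03 with array weights, -0.12 without wild-type replicate 1 and -0.07 without Δrsf2 replicate 2, STR2 at -0.03 without both arrays of high spike-in signal, and EFM3 at 0.27 without Δrsf2 replicate 2. YJR124C lay below the signal filter, at 139 ± 24.2 (SD, n = 3) in the wild type and 87.8 ± 46.9 (SD, n = 2) in Δrsf2. YJR128W, which overlaps RSF2, had no probe set of its own in the annotation used here.

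**Figure D1:**
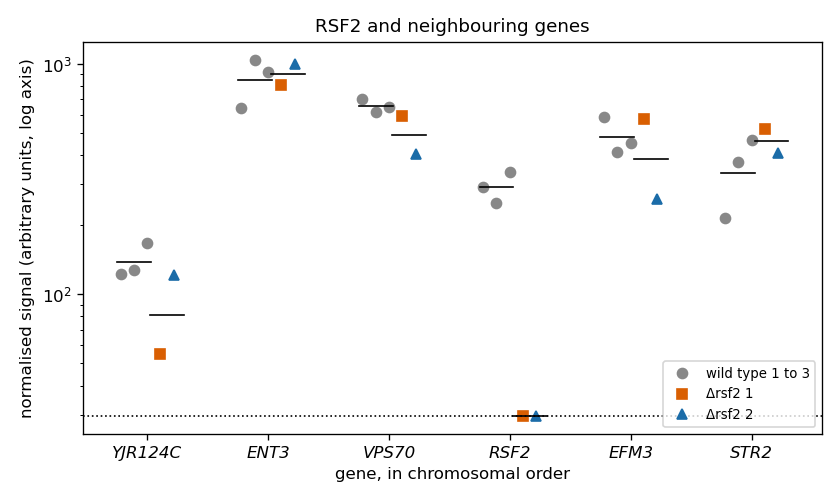
Normalised signal (arbitrary units, log axis) of RSF2 and neighbouring genes in chromosomal order; each point is 1 array, black bars are means of the log2 values per group, and the dotted line is the floor of 29.5. RSF2 lies at the floor in both Δrsf2 arrays and averages 293 in the wild type. Fitted log2 differences of the neighbours above the signal filter run from -0.42 for VPS70 to 0.47 for STR2.

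On the lower side of the comparison, HPF1 (YOL155C), which encodes a cell wall mannoprotein, had a signal of 13470 ± 4844 (SD, n = 3) in the wild type and 1149 ± 537 (SD, n = 2) in Δrsf2, 11.9-fold lower by geometric mean. GDH1 (YOR375C), the NADP-dependent glutamate dehydrogenase, was 5.91-fold lower by value, ERG4 (YGL012W), the last enzyme of ergosterol synthesis, 5.18-fold, and YHB1 (YGR234W), the flavohaemoglobin that removes nitric oxide, 7.08-fold. NDE1 (YMR145C), the mitochondrial NADH dehydrogenase that faces the cytosol, had 9514 ± 2835 in the wild type against 2789 ± 78.1 in the mutant. SUR7, a plasma membrane protein of eisosomes, had a log2 difference of -2.10 ± 0.35 (SE), SIM1, a cell wall protein, -2.26 ± 0.48, WSC2, a sensor of cell wall damage, -1.76 ± 0.38, REE1 -1.66 ± 0.37 and YJL218W -2.01 ± 0.36. RDN18-1, a gene of 18S ribosomal RNA, was at -3.14 ± 0.39. Of 10 separate control probe sets for rRNA, 9 were also lower in both mutant arrays than in every wild-type array.

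On the higher side, FMP16 (YDR070C), which encodes a protein found in mitochondria, had a signal of 4623 ± 2207 (SD, n = 3) in the wild type and 13460 ± 928 (SD, n = 2) in Δrsf2, 3.13-fold higher by value. ATG11, an adaptor of selective autophagy, was at 147 ± 24.8 against 455 ± 189, and RNY1, the vacuolar RNase, had a log2 difference of 1.43 ± 0.42 (SE). CRS5, a copper-binding metallothionein, was at 1.55 ± 0.47, and PMR1, the calcium and manganese pump of the Golgi, at 1.27 ± 0.39. The other genes of this group were KAP120, an importin-like transport factor, at 1.46, AAD10 at 1.46, MCP1 at 1.19, NQM1 at 1.21, RTC3 at 1.18, FMP40 at 1.35 and YOR186W at 2.18. NQM1 had -0.07 in the values as deposited, and the other 11 kept their sign in each alternative setting whose signal filter let them in. These genes were chosen for groups without overlap, so leaving out arrays could not change a sign.

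None of these genes passed the test. With limma, 0 of 4243 genes had an adjusted p under 0.05, the smallest was 0.154 (RSF2, HPF1 and RDN18-1), and 226 genes had an unadjusted p under 0.05, of which 59 were higher and 167 lower. By size, 64 genes were at least 2-fold higher and 165 at least 2-fold lower with no overlap between the groups, so 72.1% were lower. With arrays scaled to 1 trimmed mean and no quantile step the counts were 75 and 117, or 60.9% lower, and in the values as deposited 0 and 1004. Groups did not overlap for 848 of the 4243 genes, and chance gives 20%. The counts moved with single arrays: 111 higher and 259 lower without wild-type replicate 1, 366 and 439 without Δrsf2 replicate 1, and 322 and 652 without Δrsf2 replicate 2.

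**Figure D2:**
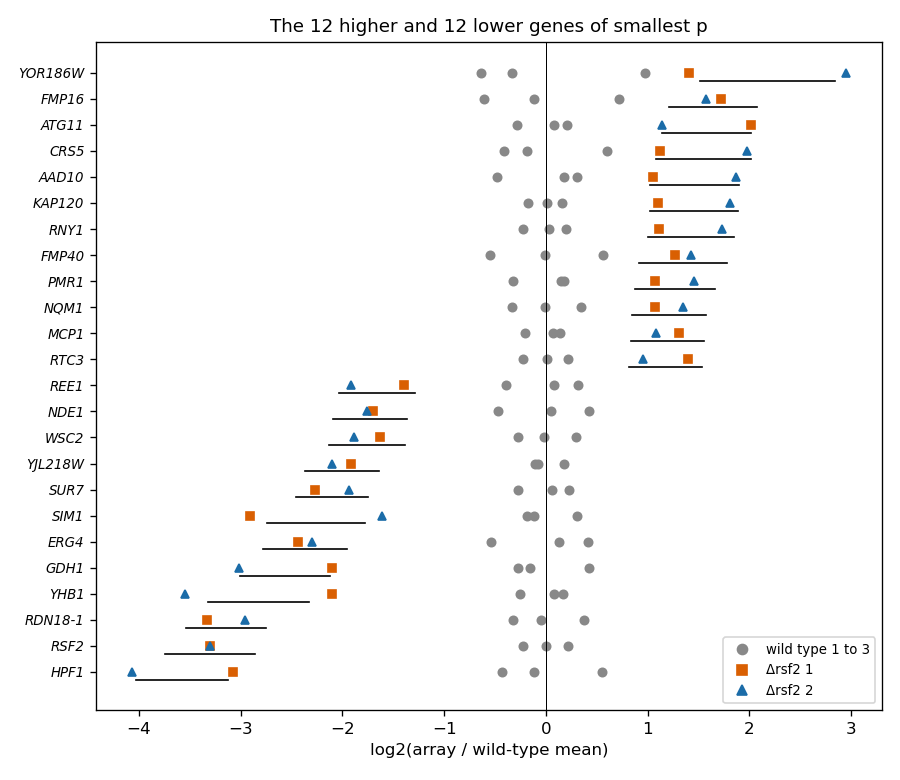
Log2 of each array over the wild-type mean for the 12 higher and 12 lower genes of smallest p; points are single arrays and black lines span the fitted difference ± 1 SE. In every gene both Δrsf2 points lie on one side of the 3 wild-type points, because genes were chosen for groups without overlap. Fitted differences reach down to -3.57 for HPF1 and up to 2.18 for YOR186W.

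Genes of respiration lay lower in Δrsf2 as groups. Of 16 genes of the tricarboxylic acid (TCA) cycle 14 were lower by value, with a median log2 difference of -0.52, and they included IDH1, a subunit of isocitrate dehydrogenase, at -1.40 ± 0.39 (SE) and MDH1, mitochondrial malate dehydrogenase, at -1.04 ± 0.33. Of 19 nuclear genes for respiratory complexes III and IV and cytochrome c 16 were lower, with a median of -0.49. Examples were COX5A, a subunit of cytochrome c oxidase, at -1.24 ± 0.34 and CYC1, the main cytochrome c, at -1.91 ± 0.64. CYC1 differed between the mutant arrays, at -0.76 in Δrsf2 replicate 1 and -3.06 in replicate 2. Of 10 dehydrogenases that feed electrons into the chain 9 were lower, with a median of -0.65, among them NDE1 and the internal NADH dehydrogenase NDI1 at -1.04 ± 0.41. The exception was NDE2, a paralog of NDE1 singled out after its value was seen, at 1.51 ± 0.76. Relative to the wild-type mean, the dehydrogenase median was -1.16 in Δrsf2 replicate 1, -0.17 in Δrsf2 replicate 2 and -0.28 in wild-type replicate 1. The groups thus overlapped in the median of this list. The subunits of succinate dehydrogenase, such as SDH3 at -0.88 ± 0.33, belong to both the TCA cycle and the dehydrogenase lists, so these lists are not independent.

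Mitochondrial ribosomal proteins and the iron regulon lay lower too. Of 68 mitochondrial ribosomal protein genes 58 were lower by value, with a median log2 difference of -0.42, and MRPL49 was at -1.26 ± 0.42 (SE) and MRPL23 at -1.14 ± 0.39. Of 19 genes that respond to low iron 17 were lower, with a median of -0.95. They included the cell wall mannoprotein FIT3 at -2.76 ± 1.03, the siderophore transporter ENB1 at -1.68 ± 0.60 and the ferric reductase FRE1 at -1.43 ± 0.45.

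For these 5 lower lists, the camera test of limma with a preset correlation of 0.01 gave adjusted p-values of 6.07e-05 for the mitochondrial ribosome, 0.000324 for the iron regulon, 0.000463 for the TCA cycle, 0.0045 for complexes III and IV and 0.0077 for the dehydrogenases. With an estimated correlation the adjusted p was 0.603 for the mitochondrial ribosome and 0.595 for the other 4, so no call held. For the TCA cycle the estimated correlation was -0.04, below the preset one, yet the unadjusted camera p rose from 5.97e-05 to 0.023. That rise cannot come from genes varying together, so a lost call need not mean that they do. The fry p of the TCA cycle was 0.00197 unadjusted and 0.061 adjusted. No member passed over all genes, and adjusted over the list alone 1 dehydrogenase (NDE1) and 0 genes of the other 4 lists passed. Wild-type replicate 1 and Δrsf2 replicate 1 had high spike-in control signals and the other 3 arrays low ones, and medians within these high and low sets were -0.61 and -0.42 for the TCA cycle, -0.22 and -0.46 for complexes III and IV and -0.89 and -0.30 for the dehydrogenases. For the mitochondrial ribosome they were -0.09 and -0.78, and for the iron regulon 0.05 and -1.72, so the iron direction did not hold in the high set. Without Δrsf2 replicate 1 the calls of the TCA cycle (median -0.38) and of the dehydrogenases (-0.17) were lost. Without Δrsf2 replicate 2 those of complexes III and IV (-0.30), the mitochondrial ribosome (-0.13) and the iron regulon (-0.30) were lost. With arrays centred on their medians the camera adjusted p was 0.0655 for the TCA cycle, 0.188 for complexes III and IV and 0.135 for the dehydrogenases.

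General stress genes and genes of glycerol synthesis lay higher in Δrsf2 by their medians over both arrays. Of 20 stress genes 18 were higher by value, with a median log2 difference of 0.63, and SSA4, a heat-induced HSP70 chaperone, was at 2.00 ± 0.66 (SE) and ALD3, an aldehyde dehydrogenase, at 2.54 ± 0.93. HSP30, a plasma membrane heat shock protein, went the other way at -2.18 ± 0.52. Relative to the wild-type mean, the stress median was 0.17 in Δrsf2 replicate 1, inside the wild-type range of -0.33 to 0.23, and 1.14 in replicate 2. The groups also overlapped for ALD3, with a signal of 1319 in Δrsf2 replicate 1 and 1427 in wild-type replicate 1. Of 4 genes that make glycerol 3 were higher, with a median of 0.78: GPD1, the main glycerol 3-phosphate dehydrogenase, at 0.79 ± 0.39 and the phosphatases GPP1 at 0.76 ± 0.53 and GPP2 at 1.14 ± 0.48, while GPD2 was at -0.40 ± 0.84. The glycerol synthesis median of wild-type replicate 1 against the wild-type mean was 0.77, as high as in the Δrsf2 arrays (0.59 and 0.79). Arginine and lysine synthesis had 11 of 14 genes higher, with a median of 0.27 and LYS9 at 0.65 ± 0.40. Its median was 0.19 in Δrsf2 replicate 2 and 0.21 in wild-type replicate 1. Haploid mating genes had 6 of 8 higher, with a median of 0.44 and the cell-cycle inhibitor FAR1 at 99.7 ± 10.3 (SD, n = 3) in the wild type and 247 ± 135 (SD, n = 2) in the mutant. Trehalose and glycogen metabolism had 14 of 16 higher, with a median of 0.31 and PIG2, a regulatory subunit of the phosphatase that acts on glycogen synthase, at 0.98 ± 0.49.

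Camera adjusted p-values were 2.54e-05 for the stress genes and 0.0349 for each of the other 4 higher lists. With an estimated correlation they were 0.595 for stress, glycerol synthesis and arginine and lysine, 0.597 for mating and 0.705 for trehalose and glycogen, so no call held, and adjusted over the list alone 0 members passed in these 5 lists. All 5 medians were negative in the values as deposited, from -0.51 for stress to -0.95 for arginine and lysine, against -1.19 for all genes, and camera pointed up for all 5 there too, with an adjusted p of 3.39e-06 for stress but 0.0896 to 0.159 for the other 4. Medians within the high and low spike-in sets were -0.00 and 1.24 for stress, 0.11 and 1.25 for glycerol synthesis, 0.12 and 0.24 for arginine and lysine, 0.66 and -0.16 for mating and -0.22 and 0.94 for trehalose and glycogen, so stress, mating and trehalose did not hold in both sets. Without Δrsf2 replicate 2 the stress adjusted p was 0.263 and the trehalose median -0.28 (0.59), and without Δrsf2 replicate 1 the mating median was -0.13 (0.985). The glycerol synthesis call was lost without wild-type replicate 2 (0.113) or 3 (0.081) and without Δrsf2 replicate 1 (0.0697) or 2 (0.449), and that for arginine and lysine without wild-type replicate 3 (0.133) and Δrsf2 replicate 1 (0.208) or 2 (0.27). The mating call was lost without wild-type replicate 1 (0.0543) or 2 (0.113) and with the spike-in set as a block (0.0801), and the trehalose call without wild-type replicate 1 (0.116) or 3 (0.0549). These 4 calls were also lost with arrays centred on their medians (0.135 to 0.201) and with scaling without quantiles (0.0654 to 0.102), and those for glycerol synthesis, trehalose and mating without a signal filter (0.0736 to 0.107) and with a stricter one (0.0764 to 0.17). The other choices of probe sets, their mean (0.0975) and plain _at sets only (0.0723), also ended the mating call, and leaving out both arrays of high spike-in signal that for arginine and lysine (0.106).

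**Figure D3:**
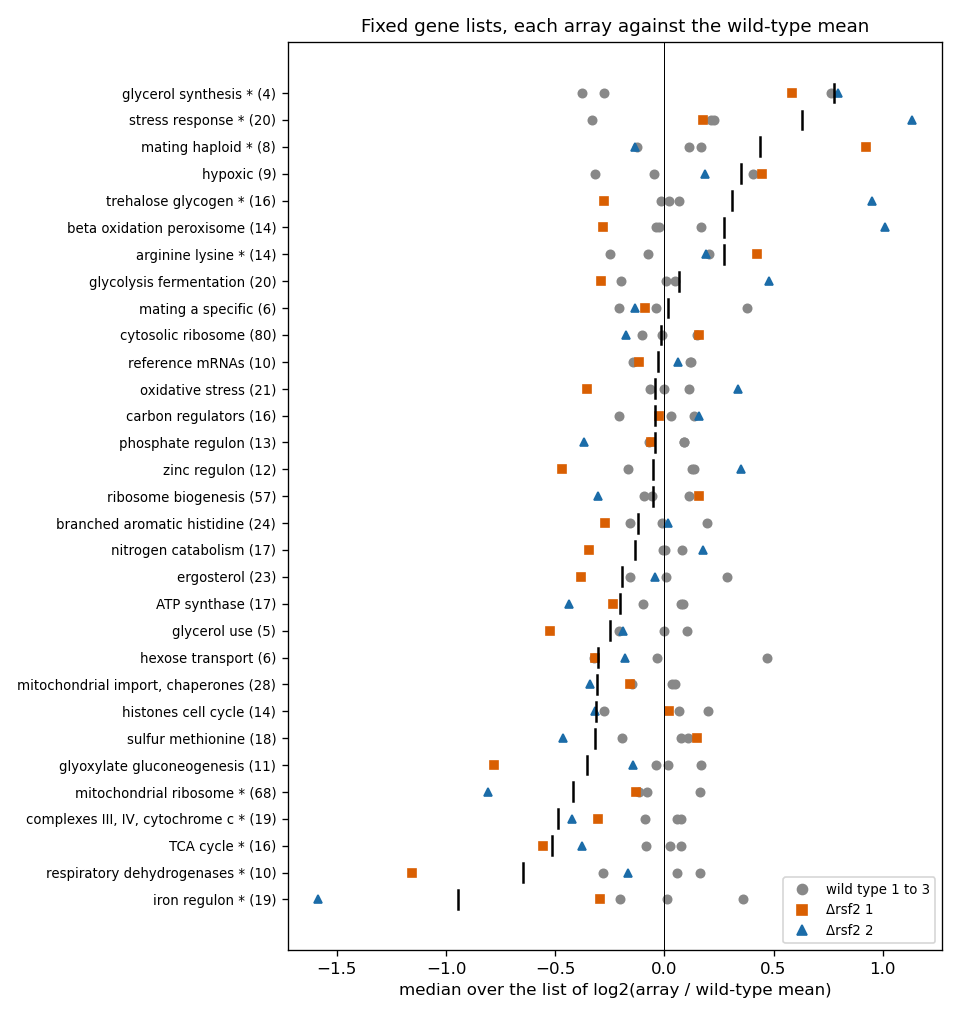
Median over each fixed gene list of log2 of the array over the wild-type mean; points are single arrays, black ticks are the median fitted difference, brackets give the genes tested, and an asterisk marks a camera adjusted p under 0.05. The 2 Δrsf2 arrays part widely for the iron regulon (-0.30 and -1.59) and for trehalose and glycogen (-0.28 and 0.95), and the medians of the 5 higher lists turn negative in the values as deposited, where that of all genes is -1.19.

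Glycerol use itself, the pathway the growth medium calls on, had 5 of 5 genes lower by value, with a median log2 difference of -0.25 and a camera adjusted p of 0.328. GUT1, glycerol kinase, was at -0.41 ± 0.36 (SE) and GUT2, the mitochondrial glycerol 3-phosphate dehydrogenase, at -0.77 ± 0.48. Glyoxylate cycle and gluconeogenesis genes had a median of -0.36 (adjusted p = 0.164), with PCK1, phosphoenolpyruvate carboxykinase, at -1.10 ± 0.35 and the carrier SFC1 at -1.23 ± 0.40. ATP synthase genes had a median of -0.20 (0.161), with ATP2 at -1.29 ± 0.47, and mitochondrial import genes -0.31 (0.139). Among regulators of carbon use, whose median was -0.04 (0.841), the respiratory activator HAP4 was at -1.19 ± 0.43 and the glucose repressor MIG1 at 1.26 ± 0.46. Ergosterol synthesis had a median of -0.20 (0.161), and adjusted over the list alone 1 of its 23 genes, ERG4, passed.

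The remaining lists also missed the camera threshold. Sulfate and methionine genes had a median log2 difference of -0.32 (adjusted p = 0.161), with SAM1, S-adenosylmethionine synthetase, at -2.33 ± 0.66 (SE) and CYS3 at -2.06 ± 0.68. Peroxisomal beta-oxidation had 0.27 (0.116), low-oxygen genes 0.35 (0.263), histone and cell-cycle genes -0.31 (0.356) and hexose transporters -0.30 (0.551). Oxidative stress genes had -0.04 (0.841), with the NADPH dehydrogenase OYE2 at -1.83 ± 0.45. Branched-chain, aromatic and histidine synthesis had -0.12 (0.651), nitrogen use -0.13 (0.841), glycolysis and fermentation 0.07 (0.263), the zinc regulon -0.05 (0.651) and the phosphate regulon -0.04 (0.855). Cytosolic ribosomal proteins had -0.02 (0.286) over the 80 of 137 genes with a probe set of their own, ribosome assembly -0.05 (0.841) and MATa-specific genes 0.02 (0.841). The median and the camera direction had opposite signs, with camera pointing up, for cytosolic ribosomal proteins, ribosome assembly, carbon regulators, oxidative stress, zinc and phosphate. mRNAs watched for RNA quality had -0.03 (0.841).

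Markers of strain and ploidy were read as values. URA3 lay at the floor in all 5 arrays, and MET17 at the floor in the wild type and at 33.1 ± 5.13 (SD, n = 2) in Δrsf2. LEU2 lay at the floor in 2 wild-type arrays and in Δrsf2 replicate 2, and at 185 in Δrsf2 replicate 1. HIS3, also listed as deleted in the parent strain, was well above the floor in each wild-type array (628, 296 and 294) and split in Δrsf2, with 72.5 in replicate 1 and 654 in replicate 2. This marker therefore does not show the deletion. OLI1, the only mitochondrially encoded gene above the signal filter, had -2.40 ± 0.91 (SE), with Δrsf2 replicate 1 at the floor, so that its distance is only a bound, and replicate 2 at -1.04. Its groups overlapped, with a signal of 170 in wild-type replicate 1 and 195 in Δrsf2 replicate 2. Carry-over into the poly(A) RNA, left open below for rRNA, was not tested for OLI1. Of the MATalpha-specific genes AFB1 was at -0.70 ± 0.49 and SAG1 at 0.12 ± 0.38, and of the meiosis genes IME1 at 0.44 ± 0.52 and NDT80 at -0.00 ± 0.59.

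The Δrsf2 arrays resembled each other less than wild-type arrays did. Across genes, which are not independent replicates, the Pearson correlation was 0.696 between the 2 Δrsf2 arrays and 0.895 to 0.938 between wild-type arrays, while Δrsf2 and wild-type arrays correlated at 0.789 to 0.876. The median SD per gene was 0.57 in Δrsf2 and 0.33 in the wild type on the log2 scale. In Δrsf2 replicate 2 set alone against the wild type, iron genes stood out, with FIT2 at -5.22, FIT3 at -4.83, FET3 at -4.20 and ARN2 at -4.25, against -0.29, -0.70, -0.57 and -0.72 in replicate 1. In replicate 1 alone, ERG8 of the mevalonate pathway was at the floor, a bound of -5.63, and IDH2 at -3.24, against -0.15 and -0.18 in replicate 2. In fits with 1 mutant array, which assume that the lone sample varies like the wild type, limma called 171 genes for replicate 1 (12 higher, 159 lower) and 27 for replicate 2 (4 higher, 23 lower). Called in both were 5 genes, all lower: RSF2, HPF1, RDN18-1, GDH1 and YHB1. Independent lists of these sizes would share 0.862 lower genes. In 100 simulations of unchanged arrays against the same controls the overlap was 0 each time. Unchanged arrays do not stand for lists of these sizes, so that 0 does not measure their overlap by chance. RSF2 is the deleted gene, so its place among the shared genes follows from the genotype. The wild-type controls were shared by both fits, so part of the excess may come from them.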

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

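The tests of 3' to 5' ratios and of rRNA controls were chosen only after the results were seen. Verdicts of 3 tests in this section depart from their written rules, a change also made after the results were seen. The verdict on other splits of the arrays, given in the next section, departs from its rule too. Both rules on labelled RNA, written beforehand, were met against that cause, for the respiratory genes with medians of -0.51 ± 0.13 and -0.44 ± 0.18 (SE across genes) in the 2 spike-in sets and for the stress genes with -0.0816 ± 0.152. The rule on rRNA was met for carry-over. They are given as open because the first 2 rest on single arrays and the third on probe sets for the same rRNA.

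Probe sets without a listed gene were not part of the comparison, and 14 of the 448 above the signal filter had a Δrsf2 mean at least 2-fold higher with no overlap between the groups, while 6 were lower by the same rule. Probe set 3982_at had deposited signals of 1.5, 1.7 and 1.9 in the wild type and of 4218.3 and 6754.2 in Δrsf2. After normalisation the Δrsf2 mean was 11438 ± 1679 (SD, n = 2), at least 8.59 higher on the log2 scale than the floor at which the wild type lay. The next was 10807_at, at 118 ± 101 in the wild type (SD, n = 3) and 373 ± 114 in Δrsf2 (SD, n = 2). These probe sets are unnamed here, and whether 3982_at detects a yeast transcript, a marker of the deletion or another introduced sequence is not known and was not tested.

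Of the respiratory transcripts, over the 41 distinct genes of the TCA cycle, complexes III and IV and the dehydrogenases, 35 were lower and 6 higher, with a median log2 difference of -0.51. The median lay at percentile 0 of 10000 random lists matched on signal, whose medians spanned -0.26 to 0.07 in their middle 95%. Genes of like signal were thus not shifted to that extent, which argues against a shift by signal alone. Other effects of the normalisation were not covered. With arrays centred on their medians the camera calls of the 3 lists were lost (adjusted p of 0.0655, 0.188 and 0.135). The 3 lists were picked as lower in the same arrays, so the percentile adds no support for the fall itself. Uneven amounts of labelled RNA are not excluded, since each spike-in set holds 1 Δrsf2 array and an error across genes is no spread between samples. The median was -0.51 in the set of high and -0.44 in that of low signal. With the set as a block and the preset correlation, camera adjusted p-values were 0.00131, 0.0079 and 0.018 for the 3 lists. Without the block, an estimated correlation gave 0.595 for each. With fewer arrays, without both of high signal, complexes III and IV kept their call, and medians were -0.42 for the TCA cycle (0.1) and -0.30 for the dehydrogenases (0.592), against -0.52 and -0.65 in all arrays. RNA degradation cannot be told apart from an effect of RSF2: the 3' to 5' ratio lay above every wild-type array for 2 of 3 control genes in Δrsf2 replicate 1 and for 1 in replicate 2, whose ratios for ACT1 (1.55) and SRB4 (3.12) were the lowest of the 5 arrays.

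The 2 Δrsf2 arrays differed in stress and storage genes. Over the 36 genes of the stress and the trehalose and glycogen lists, replicate 2 exceeded replicate 1 by a median of 1.01 ± 0.21 (SE across genes) on the log2 scale. The corresponding gap in the wild type, replicates 2 and 3 against replicate 1, which also had high spike-in signals, was -0.0816. With 1 wild-type array of high signal this has no spread between samples, so little labelled RNA as the source of the gap stays open. A difference between the cultures, such as in growth phase, was not tested.

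The lower signal of RDN18-1 was set beside other rRNA probe sets. The median of the 18S and 25S rRNA controls, scaled like the arrays, was 1389 to 1503 in the wild type and 421 and 286 in Δrsf2, and 9 of 10 of these controls were lower in both mutant arrays than in every wild-type array. These controls measure the same rRNA, so less rRNA carried over in the poly(A) RNA of the mutant samples cannot be told apart from a lower rRNA content of the cells.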

How the results depend on the processing

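The 3 alternatives on scaling without quantiles, on both arrays of high spike-in signal and on a spike-in block were chosen after seeing the data. The number of genes past the threshold was 0 in the planned and added settings, with these exceptions: 1 (RSF2) without a floor, 64 (27 higher, 37 lower) without both arrays of high spike-in signal, and 0 to 171 with single arrays left out (27 without Δrsf2 replicate 1, 171 without Δrsf2 replicate 2). RSF2 was at -6.05 (adjusted p = 0.0311) without a floor and at -3.30 (0.0207) without both arrays of high spike-in signal, and from -3.41 to -3.19 with single arrays left out. Genes higher and lower at least 2-fold numbered 0 and 1004 in the values as deposited, 112 and 226 without a signal filter, 33 and 107 with a stricter one, 382 and 437 without both arrays of high spike-in signal, 176 and 359 at 1.5-fold, and 54 to 366 and 199 to 652 with single arrays left out. Lists past the threshold numbered 10, against 3 with arrays centred on the median, 0 with an estimated correlation, 0 with fry, and 5 to 9 with single arrays left out, of which 3 to 8 were among the 10. The values as deposited reversed the medians of glycerol synthesis (-0.57), stress (-0.51), trehalose and glycogen (-0.91), arginine and lysine (-0.95) and haploid mating (-0.77), since their scaling moved the median of all genes by -1.11. With single arrays left out, trehalose and glycogen ranged from -0.28 to 0.95 and haploid mating from -0.13 to 0.92, and mating was at -0.16 without both arrays of high spike-in signal. Apart from the scaling of the deposited values, the cause was not tested. The medians of the 5 lower lists stayed below 0 in 20 of 20 settings, but camera pointed up for the mitochondrial ribosome without Δrsf2 replicate 2 (median -0.13, adjusted p = 0.915). Of 100 named genes outside the size rule, 17 changed sign in the values as deposited alone and 21 in another setting.

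Whether replicate numbers pair the samples could not be settled. With only 2 pairs, the deviations of same-numbered arrays correlated at 0.213 and -0.174 across genes. The deviations of the 2 Δrsf2 arrays from their own mean are mirror images, so these correlations cannot decide it. Both arrays numbered 1 had high spike-in signals. With a replicate block 0 genes and 9 lists were called, 8 of them among the 10, without glycerol synthesis (0.09) and arginine and lysine (0.139). Other splits of the 5 arrays into 3 and 2 are too few, at 10, for a share under 0.05. The real split gave 229 genes by the size rule and the highest other 503. At least as many came from 4 splits, the real one included. The rule written beforehand for chance, that another split gives as many, was thus met. The verdict is given as open, since so few splits cannot yield a share under 0.05. Setting wild-type replicate 3 and Δrsf2 replicate 2 apart gave 496 genes, and the split with the most was that by spike-in signal. With that signal as a block 0 genes and 10 lists were called, 9 of them among the 10, without haploid mating (0.0801). Signals near the floor limit what can be seen: RSF2, LEU2 and, in Δrsf2 replicate 1, OLI1 and ERG8 have only a bound.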

Other observations

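Cell wall genes were not among the lists fixed beforehand, and HPF1, SIM1 and WSC2 among the lower genes raised the hypothesis that others may lie lower too. A list of 50 cell wall genes was written before it was tested. Without those 3 genes, 43 were tested: 29 were lower and 14 higher by value, with a median log2 difference of -0.48 and an unadjusted camera p of 0.018 (p = 0.067 with an estimated correlation). These are not to be set beside the adjusted values of the fixed lists. Unadjusted, the TCA cycle had camera p-values of 5.97e-05 and, with an estimated correlation, 0.023. SCW4, a glucanase-like wall protein, was at -1.22 ± 0.34 (SE), TOS1 at -1.17 ± 0.36, the glucanosyltransferase GAS1 at -1.75 ± 0.55 and FKS1, a glucan synthase subunit, at -0.65 ± 0.36. PST1 went the other way at 0.93 ± 0.38, and CWP2 was at -0.04 ± 0.25. Medians were -0.40 in Δrsf2 replicate 1 and -0.27 in replicate 2. The genes were named here after their values were seen, and the lists and the idea come from the same 5 arrays.

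Single genes stood far from the wild type in Δrsf2 replicate 2. Set alone against the wild type, that array had log2 differences of -3.87 for the metalloreductase FRE7 and -2.58 for the iron permease FTR1, and of 4.31 for the kinase gene FMP48 and 4.07 for ALD3, against -0.84, 0.51, 0.24 and 1.01 in replicate 1. The limma adjusted p-values of these 4 genes in that fit were under 0.05, and the lone array was assumed to vary like the wild type. Among wall genes CIS3 was at -3.14 and SCW10 at -3.14, while PIR3 was at 2.91 and SPI1 at 2.24, against -0.06, 0.09, 0.59 and -0.35 in replicate 1.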
